A study of Mus musculus with 17 samples.

How the data were processed

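Messenger RNA of 17 samples of CD-1 mouse cells was sequenced, with Trizol extraction and the Illumina TruSeq mRNA kit named in the labels' protocols. The deposited files give whole-number read counts per gene, which the authors made with HTSeq 0.6.1 per the submitters' processing notes. The same notes name FastQC 0.11.3, Trimmomatic 0.32, TopHat2 2.0.12 and genome build mm9. Their order, the parameters and the gene annotation are not given in the sources used here. The strand setting of the counting is not given either. Values of antisense and overlapping genes, and of genes with near-identical paralogs or pseudogenes, are therefore uncertain. TopHat2 aligns across splice junctions and HTSeq counts reads that fall in 1 gene, so reads shared by gene copies leave the counts of those copies low.

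Each file listed 24015 genes by symbol, of which 3443 had 0 counts in every library. It also held 5 lines of the counter itself, 2 of them at 0 in every library. These lines, for reads without a feature, with an ambiguous feature or without a unique position, took up 20.8% to 33.1% of each file's total and were left out of library sizes and tests. Reads without a unique position alone made up 13.7% to 24.6%. Counts in genes came to 20071567 to 45914262 per library, and 15176 to 17683 genes had at least 1 count. Before TMM scaling, 3 counts in a library corresponded to between 0.0653 and 0.149 CPM. No coordinates are given, since genes were matched by symbol and the reference at hand was of another build.

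Groups were taken from the sample labels: 3 MEF libraries, 3 XEN and 4 iXEN libraries in ESC medium, and 3 XEN and 4 iXEN libraries in XEN medium. The series' design text calls the samples biological replicates, and nothing further says that they came from separate cultures or derivations. The p-values therefore measure only the spread between these libraries. Libraries of a group were compared pairwise by a chi-square statistic over their counts, which came to 46.1 to 1301 per degree of freedom. No pair agreed within sampling noise, and each library was counted as 1 replicate. The labels give no sequencing date or batch.

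The groups, the comparisons and tests, the gene lists, the rule for named genes and most of the alternative settings were fixed before the data were examined. There were 7 comparisons. iXEN and XEN cells in ESC medium were each set against MEF, which were kept in MEF medium. Cell type, medium and number of passages differ together there and cannot be told apart. iXEN cells were set against XEN cells in either medium, and XEN medium against ESC medium in either cell type. The last comparison was the interaction of cell type and medium. Each of the 7 was tested with edgeR 4.0.16 in R 4.3.3. Only the libraries of the groups compared entered a fit. Genes were kept by filterByExpr on the group (minimum count 10, minimum total 15), libraries were scaled by TMM factors (0.863 to 1.16), and the quasi-likelihood test was two-sided with Benjamini-Hochberg adjustment at 0.05. A gene is said to have risen or fallen, or to be called, when its adjusted p is under 0.05. Fold changes are log2 values of the fit. SE is the log2 fold change divided by the square root of the F statistic, and 95% intervals use the total degrees of freedom of the same fit. CPM are counts scaled by library size and by TMM factors computed over all 17 libraries, and the logCPM used for gene lists and correlations have a prior count of 2.

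Where all libraries of a group had 0 counts of a gene, the fold is a lower bound against a floor of 3 counts over the group. With 1 to 3 counts, the ratio of counts per library size is given with its exact 95% counting interval. Intervals of ratios and floors cover counting error only, since counts were pooled over the libraries of a group and the spread between libraries was left out. The reads also carry no molecular identifiers. The share of genes whose groups do not overlap is given beside the share that chance gives.

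The 28 gene lists were XEN core, visceral endoderm, parietal endoderm, pluripotency, reprogramming factors, fibroblast, epithelial, trophoblast, primitive streak, neural, macrophage, endothelial, cell cycle, p53 and CDK inhibitors, imprinted, sex-linked, Hox, cholesterol synthesis, STAT3 response, FGF-ERK response, BMP and Nodal, WNT response, hypoxia and glycolysis, integrated stress response, NRF2 response, interferon, germline and DNA methylation machinery. They were written from general knowledge, and some genes stand in more than 1 list. Of 441 symbols, 440 were found, 2 of them under another symbol (Spink3 for Spink1, Emr1 for Adgre1), and 1 was not analysed here. Members were counted as called over all genes tested and adjusted over the list alone. Lists with at least 5 tested members were tested against the other genes with limma 3.58.1 camera at a preset correlation of 0.01. The test was run for 26 lists and not for the reprogramming factors and sex-linked lists. The 169 tests were adjusted together by Benjamini-Hochberg. With the correlation estimated from the data, 0 of the 54 list calls held, and 0 lists passed with the block or without libraries left out, so every list call in the text rests on the preset value. Medians of a list with and without libraries are over the members tested both ways, and those at a kept call are given where they moved by over 1.5 times. Ranges in brackets after the median of a list are the quartiles of its members; why a call was lost where the median stayed about as large was not tested.

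Named genes followed a rule. Per comparison it took the 8 highest and the 8 lowest log2 fold changes among called genes with an average logCPM of at least 3 and groups that did not overlap, passing over symbols of unnamed gene models. It added the 3 called members with the largest change in the direction of each called list, and 15 genes whatever their result: Gata4, Gata6, Sox17, Sox7, Pdgfra, Dab2, Afp, Ttr, Thy1, Cdh1, Nanog, Pou5f1, Sox2, Klf4 and Myc. Fewer than these are given, from the top of each part, and a few genes that the rule takes are not reported here. Genes outside the rule are marked as chosen after their values were seen.

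XEN and iXEN libraries carry the same numbers in both media. Whether these pair the libraries was checked from the correlation of their deviations from the group means over 10753 genes (mean logCPM of at least 1), before any fits were compared. For XEN cells the pairing comes from this check alone: the same numbers correlated at 0.27, 0.33 and 0.62, each over the threshold of 0.1. XEN ESC medium 2 correlated more with XEN XEN medium 1 (0.41). For iXEN cells not every number passed. By this threshold the number counts as pairing XEN libraries across media only. Deviations from the mean of so few libraries are tied to each other, so the check does not tell XEN numbers 1 and 2 apart. The block was an alternative in both cell types, since the protocols name no paired design.

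The procedure was tested on simulated data with the means, library sizes and spread of each comparison and 50 genes changed by each of 2-, 4-, 8- and 16-fold. The shares recovered were 8%, 66%, 86% and 94% for iXEN against MEF (14352 genes) and 0%, 4%, 18% and 38% for XEN against MEF (14001 genes). They were 0%, 8%, 56% and 88% for iXEN against XEN in ESC medium (12944 genes) and 0%, 4%, 36% and 58% in XEN medium (13263 genes). For the medium they were 0%, 0%, 16% and 42% in XEN cells (13241 genes) and 0%, 32%, 58% and 88% in iXEN cells (12920 genes), and for the interaction 0%, 4%, 8% and 38% (14357 genes). Far fewer genes were changed in these runs than were called against MEF. The shares for the comparisons against MEF may therefore be too low. Unchanged genes called in these 7 runs numbered 8, 1, 3, 2, 3, 5 and 0. A comparison without calls therefore leaves room for changes of 2-fold and often of 8-fold. Of 40 random gene sets per comparison, 0, 1, 1, 0, 2, 4 and 2 had a camera p under 0.05. The simulated genes were drawn independently of each other. These sets therefore do not test the preset correlation on which the list calls rest.

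The alternative settings chosen at that point were RLE size factors in place of TMM, no expression filter, DESeq2 1.42.0 (Wald test at an alpha of 0.05), 1 fit over all 17 libraries, an added threshold of a log2 fold change of at least 1, the number as a block, the XEN-medium libraries in place of the ESC-medium libraries against MEF, and leaving out each library in turn. After the data were seen, fits without libraries that held fibroblast collagens (XEN ESC medium 1, iXEN XEN medium 2 and 9), without XEN 7, and without both were added. Without both, XEN 2 was the lone XEN library in ESC medium, and for the interaction in each medium. These fits pool the spread, so the lone library is assumed to vary like the other groups. The list tests and the overlap of the comparisons against MEF were also run under these settings, and the list tests with RLE size factors and with the block. RLE in place of TMM moved the median of all genes by at most 0.0510 on the log2 scale.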

Results

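RNA-seq counts per gene were obtained for 17 libraries of CD-1 mouse cells. Mouse embryonic fibroblasts (MEF), the connective tissue cells usually taken as the starting point of reprogramming, gave 3 libraries after 3 passages in MEF medium. XEN cells, which are stem cell lines of the extraembryonic endoderm that forms the yolk sac linings, gave 3 libraries in ESC medium and 3 in XEN medium. Induced XEN (iXEN) cells, obtained with the OSKM reprogramming factors Pou5f1 (Oct4), Sox2, Klf4 and Myc, gave 4 libraries in each medium. XEN and iXEN cells were kept for 10 passages in ESC medium and then for 5 passages in ESC medium or in XEN medium. Libraries are named by cell type, medium and the number in their labels: 1, 2 and 7 for XEN cells, and 1, 2, 6 and 9 for iXEN cells. Counts in genes came to 20071567 to 45914262 per library (n = 17). The range was 25871507 to 33893638 in MEF, 20071567 to 42349804 in XEN cells and 21752277 to 42949297 in iXEN cells in ESC medium, and 37544512 to 45914262 in XEN cells and 26368023 to 38523328 in iXEN cells in XEN medium.

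The first comparison asked how far iXEN cells had moved away from fibroblasts. MEF were in MEF medium and had fewer passages, so medium and passages are not separated from cell type here. In ESC medium, iXEN cells held more transcripts of most extraembryonic endoderm regulators named here than MEF. Gata4, a zinc finger transcription factor of primitive endoderm, was at 1071 ± 146 CPM (SD, n = 4) against 1.22 ± 0.259 CPM in MEF (SD, n = 3), a log2 fold change of 9.81 (SE 0.33, edgeR adjusted p = 6.15e-07). Sox17, an endoderm transcription factor, rose by 9.81 (SE 0.60), and Lama1, a laminin chain of the basement membrane laid down by parietal endoderm, rose from 36.3 ± 4.93 to 24832 ± 5381 CPM. Thy1, a surface glycoprotein of fibroblasts, fell from 282 ± 136 to 0.284 ± 0.0788 CPM (log2 fold change -9.94, SE 0.51).

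Of the 14 tested members of the XEN core list, 13 rose and 0 fell (median log2 fold change 8.62, adjusted p = 1.58e-10; adjusted p = 0.333 with an estimated correlation). Among them were Gata6, at 4.80 (SE 0.27), Sox7, at 8.10 (SE 0.25), and the endocytic adaptor Dab2, at 2.50 (SE 0.22). The exception was the growth factor receptor Pdgfra, at 794 ± 277 CPM in iXEN cells and 633 ± 118 CPM in MEF (0.36, 95% interval -0.34 to 1.06). Of 17 visceral endoderm genes, which serve nutrient uptake and transport, 16 rose (median 4.64, adjusted p = 1.64e-06; adjusted p = 0.537 with an estimated correlation). The thyroxine carrier Ttr reached 80.6 ± 66.8 CPM (8.56, SE 1.03) and the signal Ihh 79.6 ± 39.6 CPM (8.68, SE 0.67). Hnf4a had 2 counts over the MEF libraries, which gave a ratio of 1335 (95% counting interval 369 to 11027). The secreted protein Afp had 3 counts in MEF, and the ratio was 229 (78.3 to 1115). Of 15 parietal endoderm genes, 14 rose (median 3.90, adjusted p = 2.96e-07; adjusted p = 0.333 with an estimated correlation), with the proteoglycan Srgn at 9.25 (SE 0.35) and the retinol receptor Stra6 reaching 271 ± 123 CPM.

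Junction and keratin genes of the epithelial list moved the same way, with 14 of 16 higher (median 6.04, adjusted p = 1.05e-06; adjusted p = 0.594 with an estimated correlation). The tight junction gene Cldn6 rose by 9.57 (SE 1.68), the adhesion gene Epcam by 8.09 (SE 0.77) and E-cadherin (Cdh1) by 3.02 (SE 0.66), while Prss8 had 1 count in MEF and a ratio of 1407 (252 to 55618). In the endothelial list 5 of 7 genes rose and 1 fell (median 3.90, adjusted p = 0.0209; adjusted p = 0.605 with an estimated correlation). Cdh5, Esam and Tek, which are known from vessel walls, rose by 6.48, 6.91 and 3.97. In the cell cycle list 12 of 24 genes rose and 0 fell (median 0.87, adjusted p = 0.000689; adjusted p = 0.737 with an estimated correlation), among them the replication licensing genes Cdc6 (3.12, SE 0.53), Mcm2 (1.91, SE 0.24) and Mcm3 (1.54, SE 0.20).

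All 26 fibroblast genes fell (median -9.56, adjusted p = 4.91e-14; adjusted p = 0.333 with an estimated correlation). The homeobox gene Meox2 was at least 1230-fold lower, the collagen-binding proteoglycan Lum fell from 717 ± 433 to 0.198 ± 0.0700 CPM, and the collagen cross-linking enzyme Lox fell from 2171 ± 621 to 0.684 ± 0.0872 CPM. Of 30 Hox genes, which set position along the body axis, 26 fell (median -6.42, adjusted p = 1.62e-10; adjusted p = 0.537 with an estimated correlation), and Hoxb2, Hoxd4 and Hoxb5 were at least 163-fold, 164-fold and 109-fold lower. Of 13 macrophage genes, 12 fell (median -6.67, adjusted p = 2.34e-05; adjusted p = 0.607 with an estimated correlation). The complement gene C1qa was at 9.01 ± 4.68 CPM in MEF and at least 376-fold lower in iXEN cells.

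Of 23 imprinted genes, which are read from the copy of 1 parent, 14 fell and 2 rose (median -3.36, adjusted p = 0.0243; adjusted p = 0.688 with an estimated correlation). The growth factor Igf2 fell from 8930 ± 995 to 10.7 ± 13.0 CPM, and Dlk1 and Mest fell by 10.56 and 7.44 on the log2 scale. Of 18 genes of cholesterol synthesis and uptake, 16 fell (median -2.38, adjusted p = 2.15e-05; adjusted p = 0.634 with an estimated correlation), with the isoprenoid enzymes Idi1 and Fdps at -4.00 and -3.27. Of 16 interferon response genes, 12 fell (median -3.76, adjusted p = 2.34e-05; adjusted p = 0.618 with an estimated correlation), among them Ifit1 (-8.03), Ifit3 (-7.29) and Ifit2 (-6.80). Adjusted over the list alone, the counts of these 12 lists were unchanged except that 13 interferon genes fell and 1 epithelial gene fell.

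Of the reprogramming factors, Pou5f1 rose from 0.0611 ± 0.0479 CPM in MEF to 0.801 ± 0.301 CPM in iXEN cells (3.70, adjusted p = 0.00204), and Klf4 rose from 152 ± 30.3 to 371 ± 137 CPM (1.32, adjusted p = 0.00969). Sox2 fell from 2.46 ± 1.17 to 0.0360 ± 0.0102 CPM (-5.98, adjusted p = 6.12e-05). Myc was at -0.74 (95% interval -1.67 to 0.19) and the pluripotency factor Nanog at -1.04 (adjusted p = 0.0534). Nanog was called lower by edgeR with RLE size factors (adjusted p = 0.0488) and without iXEN ESC medium 9 (0.0324), and by DESeq2 (0.0442). Under the other settings it was not called. The counts of the reprogramming factors do not separate endogenous from introduced copies. Outside the lists, the annexin gene Anxa13 was at least 420-fold higher, with 0.0461 CPM in iXEN ESC medium 6, and the retinoic acid-degrading enzyme Cyp26a1 rose by 10.74 (SE 2.33), at 2.09 to 355 CPM. The interleukin receptor gene Il1rl2 was at least 1325-fold lower, Ifi204, which shares sequence with its neighbours in an interferon-inducible family, at least 1108-fold, and the angiotensin receptor Agtr2 fell by 12.52 on the log2 scale.

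**Figure D1:**
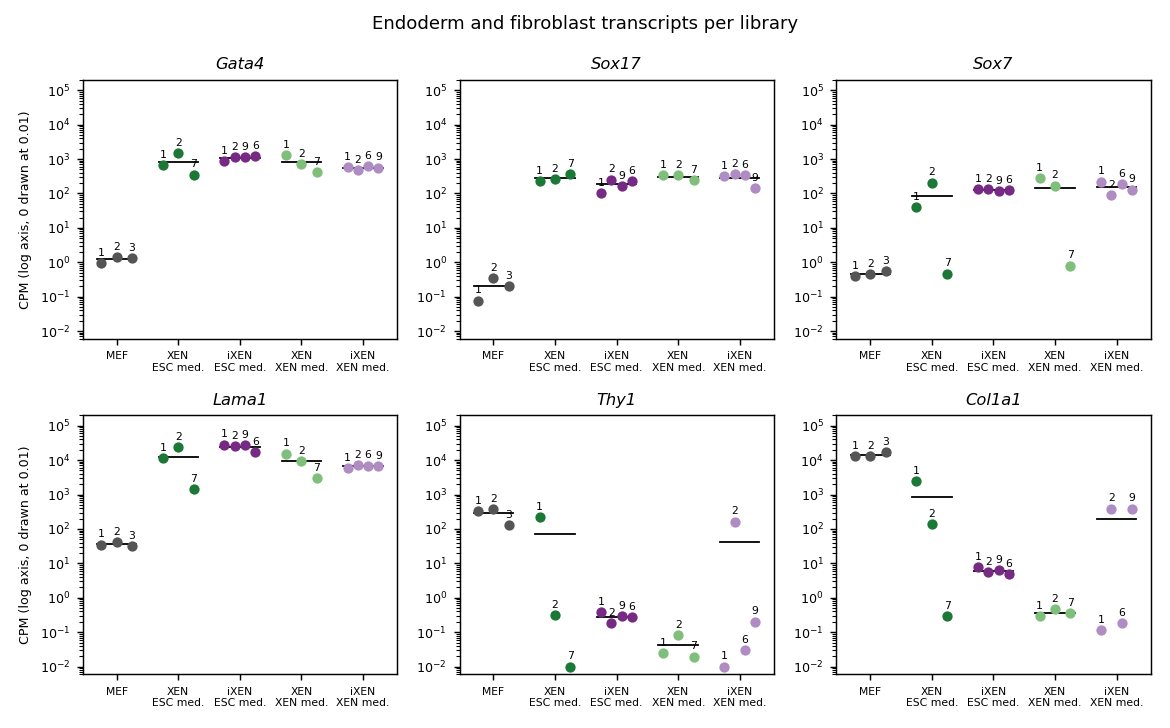
CPM (log axis, 0 drawn at 0.01) of Gata4, Sox17, Sox7, Lama1, Thy1 and Col1a1 in each of the 17 libraries, grouped by cell type and medium; points carry the library number and black lines are group means. Gata4 averaged 1.22 CPM in MEF and 1071 CPM in iXEN cells in ESC medium, Sox7 lay at 0.470 and 0.805 CPM in XEN 7, and Thy1 lay at 216 CPM in XEN ESC medium 1 and 163 CPM in iXEN XEN medium 2.

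edgeR's quasi-likelihood test called 6704 of 14352 genes in this comparison, 2985 higher and 3719 lower in iXEN cells. The CPM of the groups did not overlap for 55.1% of the genes tested, where chance gives 5.71%. With the iXEN libraries in XEN medium in place of those in ESC medium, Sox2 lay at 2.45 (adjusted p = 0.459), so its direction depended on the libraries used.

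XEN cells were compared with the same MEF to give the profile of the established endoderm line, with the same limit of medium and passages. Sox17 rose from 0.207 ± 0.131 CPM in MEF (SD, n = 3) to 285 ± 76.3 CPM in XEN cells in ESC medium (SD, n = 3), a log2 fold change of 10.46 (SE 0.65, edgeR adjusted p = 0.00248). Gata4 rose to 830 ± 586 CPM (9.46, SE 0.77) and Gata6 to 268 ± 126 CPM (4.44, SE 0.44). Igf2 fell from 8930 ± 995 to 2.74 ± 2.50 CPM (-11.63, SE 1.88). Thy1 was at 72.1 ± 125 CPM, with 216 CPM in XEN ESC medium 1, and its log2 fold change was -1.91 (95% interval -7.56 to 3.74); without that library it was -10.95 (adjusted p = 0.0115).

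Of 14 XEN core genes, 11 rose (12 adjusted over the list alone; median 8.22, adjusted p = 1.33e-08; adjusted p = 0.537 with an estimated correlation). Foxq1, a forkhead transcription factor, rose by 9.51 (SE 0.50) and Sox7 by 7.49 (SE 1.97), although XEN ESC medium 7 held 0.470 CPM of Sox7 against a group mean of 82.6 ± 109. Dab2 lay at 1.85 (adjusted p = 0.0528) and Pdgfra at -1.06 (95% interval -3.28 to 1.16), with 25.5 CPM of Pdgfra in XEN ESC medium 7. Dab2 was called by edgeR with RLE size factors (adjusted p = 0.0476), by DESeq2 (0.00665) and under some other settings, but not under all. Of 14 visceral endoderm genes, 9 rose (11 adjusted over the list alone; median 4.90, adjusted p = 9.99e-06; adjusted p = 0.537 with an estimated correlation). Ttr reached 41.0 ± 30.5 CPM (7.60, SE 1.06), while Hnf4a, Afp and the protease inhibitor Spink3 had 2 or 3 counts in MEF and ratios of 1275 (353 to 10534), 1406 (481 to 6821) and 690 (236 to 3348). Of the 35.4 CPM of Afp, most came from XEN ESC medium 7, at 103 CPM.

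Of 15 parietal endoderm genes, 8 rose (median 4.22, adjusted p = 0.000612; adjusted p = 0.706 with an estimated correlation), with Stra6 at 9.12 (SE 0.62), Srgn at 9.02 (SE 0.93) and Lama1 at 8.45 (SE 1.25). Of 12 epithelial genes, 8 rose and 1 fell (median 5.98, adjusted p = 0.000894; adjusted p = 0.605 with an estimated correlation). The keratin genes Krt8 (8.40) and Krt18 (8.44), whose reads can be shared with processed pseudogenes, reached 1398 ± 1306 and 1081 ± 1554 CPM. Cdh1 was at 214 CPM in XEN ESC medium 7, and its log2 fold change was 5.74 (95% interval -0.04 to 11.51). Of 7 endothelial genes, 5 rose and 1 fell (median 4.41, adjusted p = 0.0399; adjusted p = 0.605 with an estimated correlation). Cdh5 reached 123 ± 20.5 CPM, and Vwf, a blood clotting factor, was at 624 CPM in XEN ESC medium 7 within a group mean of 217 ± 353. In the cell cycle list 4 of 24 genes rose (median 0.86, adjusted p = 0.000946; adjusted p = 0.790 with an estimated correlation), led by Cdc6 at 2.23, Mcm2 at 1.56 and Mcm3 at 1.42.

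Of 26 fibroblast genes, 9 fell (12 adjusted over the list alone; median -3.89, adjusted p = 4.73e-06; adjusted p = 0.672 with an estimated correlation). Lum fell by 7.70 on the log2 scale and Meox2 had 1 count in XEN cells, a ratio of 2553 (458 to 100893). XEN ESC medium 1 held 2403 CPM of the collagen gene Col1a1 and 1470 CPM of Col3a1. Of 30 Hox genes, 8 fell (9 adjusted over the list alone; median -2.64, adjusted p = 4.35e-05; adjusted p = 0.605 with an estimated correlation), among them Hoxd13 (-5.44), Hoxd10 (-5.34) and Hoxd3 (-3.89). Of 13 macrophage genes, 9 fell (median -6.28, adjusted p = 1.24e-05; adjusted p = 0.607 with an estimated correlation), with C1qa at least 260-fold and Emr1 at least 241-fold lower. Of 23 imprinted genes, 7 fell and 0 rose (10 and 1 adjusted over the list alone; median -3.04, adjusted p = 0.000385; adjusted p = 0.618 with an estimated correlation). The noncoding RNA gene H19 fell from 9636 ± 890 to 25.8 ± 11.4 CPM. Of 18 cholesterol genes, 14 fell (median -1.88, adjusted p = 2.15e-05; adjusted p = 0.605 with an estimated correlation), with Lss at -2.76. Of 16 interferon genes, 1 fell, Ifi44 (-4.48; list median -1.74, adjusted p = 0.0111; adjusted p = 0.797 with an estimated correlation).

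Outside the lists, the gastrokines Gkn1 and Gkn2, secreted proteins of stomach lining, rose by 13.14 (SE 2.79) and 11.28 (SE 1.60), with SDs above their means (2530 ± 4117 and 3038 ± 3869 CPM). Trap1a rose to 353 ± 35.9 CPM (10.35, SE 0.36). The growth factor gene Gdf10 was at least 950-fold lower and the limb transcription factor Tbx4 at least 778-fold lower. Sox2, Nanog, Klf4 and Myc lay at 0.53, 0.19, 0.40 and -0.21 (adjusted p = 0.810, 0.882, 0.412 and 0.551), and Pou5f1, at 3.99 ± 4.53 CPM, was below the expression filter.

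edgeR called 3507 of 14001 genes, 1591 higher and 1916 lower in XEN cells, and groups did not overlap for 53.4% of genes, where chance gives 10%. The count was 372, 692 and 562 without MEF 1, 2 and 3, 6056 without XEN ESC medium 2, 5850 by DESeq2 and 6830 with the XEN-medium libraries. The endothelial call was lost without XEN ESC medium 1 (adjusted p = 0.107), where the list median was 3.93 (quartiles 1.37 to 4.99) against 4.41 (1.98 to 5.94) with it, so the loss does not tie the list to that library. Without that library the medians of the fibroblast (-3.89 to -7.30) and interferon lists (-1.74 to -4.37) moved at a kept call. Without XEN 7 the interferon median went from -1.74 to -1.07, and the pluripotency list passed upward (median 0.973 to 1.002, adjusted p = 0.0470; 0.653 with an estimated correlation). Sox2 changed sign in XEN medium (-6.95).

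The genes that changed against MEF were then compared between iXEN and XEN cells. Of 13913 genes tested in both comparisons, 6449 were called for iXEN cells and 3492 for XEN cells, and all 2974 called in both moved the same way, 1257 higher and 1717 lower. Sox17, Gata4, Lama1 and Stra6 were among the shared rises, and Igf2, Meox2 and Lum among the shared falls. Independent lists of these sizes would share 310 higher and 511 lower genes. The log2 fold changes had a Pearson correlation of 0.862 across genes, which are not independent replicates. Simulations that drew MEF, iXEN and XEN libraries alike around the MEF means gave 0.193 and 0 shared calls (means of 20 simulations). They show what shared controls give where nothing changed, and do not measure how alike iXEN and XEN cells are. The covariance was 5.54 against 0.0378 simulated, a difference of 5.50. The 3 MEF libraries were too few to be split, so part of the excess of shared calls over independent lists may come from the shared controls. The medium and passages in which both cell types differed from MEF may add to it too.

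**Figure D2:**
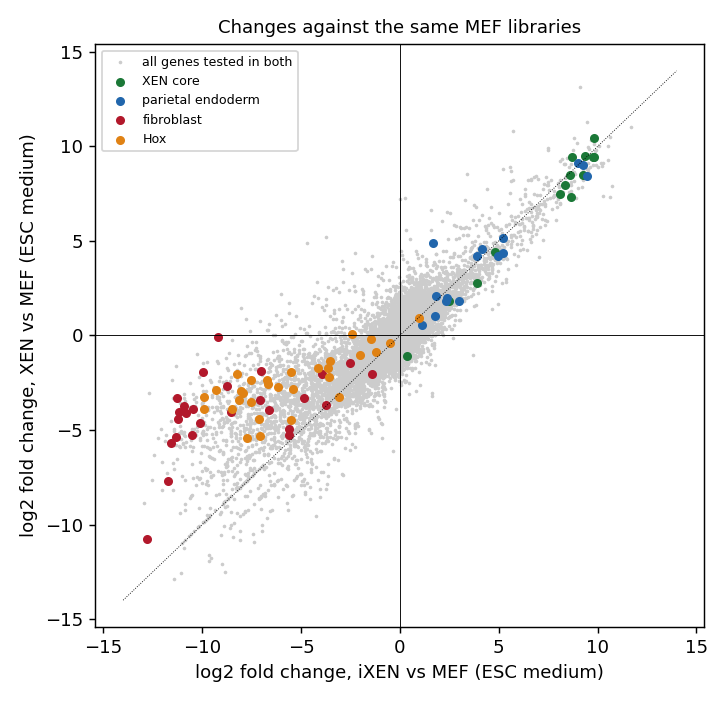
Log2 fold change against MEF of each gene tested in both comparisons, iXEN cells on the x axis and XEN cells on the y axis, both in ESC medium; grey points are all genes, coloured points the XEN core (green), parietal endoderm (blue), fibroblast (red) and Hox (orange) lists, and the dotted line marks equal change. The median of the fibroblast list was -9.56 on the x axis and -3.89 on the y axis, and that of the XEN core list 8.62 and 8.22.

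The libraries of XEN and iXEN cells varied more among themselves than those of MEF. The biological coefficient of variation was 0.195 in MEF, 0.598 in XEN and 0.418 in iXEN cells in ESC medium, and 0.523 and 0.548 in XEN medium. Correlations of log2 CPM were taken over all pairs of libraries, which for XEN and iXEN cells pool both media. The median was 0.986 between MEF libraries, 0.775 between XEN libraries, 0.8291 between iXEN libraries and 0.827 between XEN and iXEN libraries. Each of the last 3 lay above the correlation of MEF with XEN (0.576) and with iXEN libraries (0.577). The first principal components took up 43.3% and 17.6% of the variance.

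Several libraries stood apart in single gene groups; the genes given here were chosen after their values were seen. Fibroblast collagen transcripts were present in XEN ESC medium 1, iXEN XEN medium 2 and iXEN XEN medium 9. Col1a1 lay at 2403, 393 and 391 CPM in them, against 14384 CPM in MEF and at most 137 CPM in the other 11 XEN and iXEN libraries. Postn, a matrix protein of fibroblasts, was at 489 and 189 CPM in the first pair of these libraries and at 0.0579 CPM in iXEN XEN medium 9, while Igf2 was at 4.95, 6.96 and 0.0290 CPM. XEN 7 had 0.470 and 0.805 CPM of Sox7, 214 and 164 CPM of Cdh1, and 716 and 1091 CPM of the X-inactivation RNA Xist in ESC and XEN medium. iXEN XEN medium 9 held 58.4 CPM of Pou5f1 and 48.2 CPM of Sox2, where no other XEN or iXEN library exceeded 8.99 and 7.25 CPM. Y-linked genes (Ddx3y, Eif2s3y, Kdm5d and Uty summed) were at 0.261 CPM in iXEN ESC medium 9 and 61.4 CPM in iXEN XEN medium 9.

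**Figure D3:**
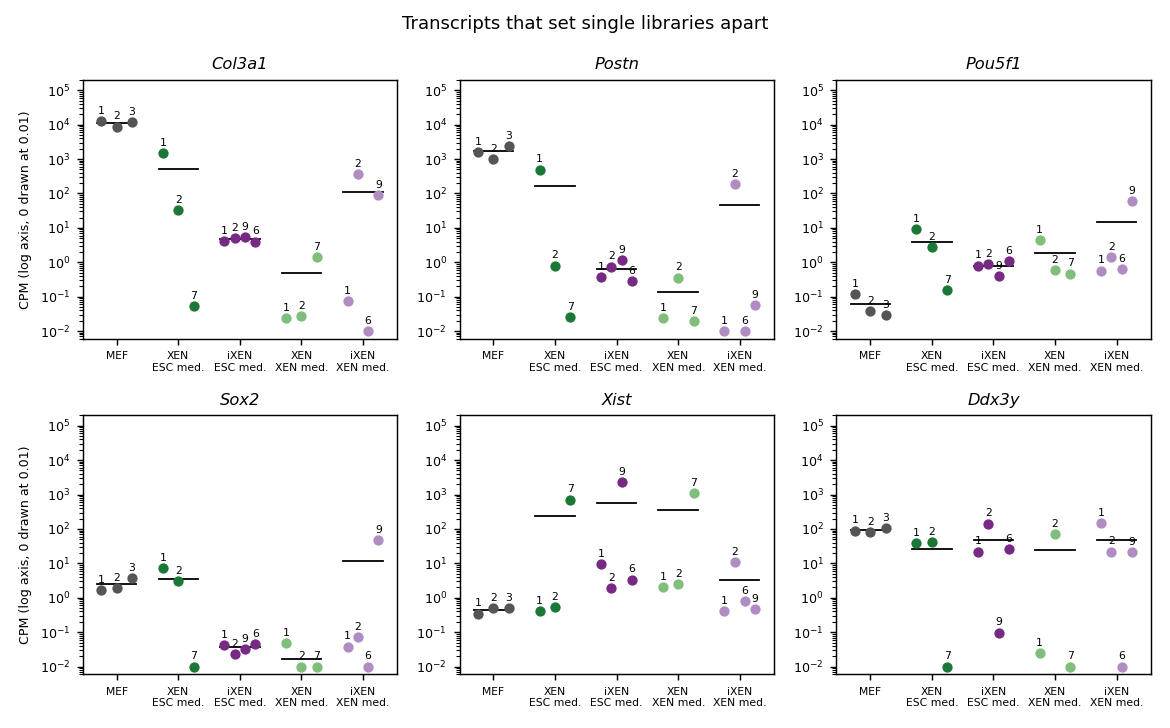
CPM (log axis, 0 drawn at 0.01) of Col3a1, Postn, Pou5f1, Sox2, Xist and Ddx3y in each of the 17 libraries, grouped by cell type and medium; points carry the library number and black lines are group means. Col3a1 lay at 1470 CPM in XEN ESC medium 1 and Pou5f1 at 58.4 CPM in iXEN XEN medium 9, and the genes were chosen after their values were seen.

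Next, iXEN cells were set against XEN cells in ESC medium to see how far the induced lines differ from the established ones. For none of the endoderm regulators named here did the 95% interval of the difference exclude 0. Gata4 was at 1071 ± 146 CPM in iXEN cells (SD, n = 4) and 830 ± 586 CPM in XEN cells (SD, n = 3), a log2 difference of 0.35 (95% interval -0.72 to 1.43). Gata6 lay at 0.36 (-0.46 to 1.18), Sox17 at -0.64 (-1.49 to 0.20), Dab2 at 0.66 (-0.43 to 1.75) and Sox7 at 0.62 (-2.20 to 3.44). These intervals leave room for differences of more than 2-fold. Afp lay at -2.42 (-6.05 to 1.21), Cdh1 at -2.71 (-6.57 to 1.16), Pou5f1 at -2.34 (-4.78 to 0.09) and Klf4 at 0.92 (-0.01 to 1.85).

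Among lists, fibroblast genes were lower in iXEN cells (median -5.19, adjusted p = 0.000113; adjusted p = 0.634 with an estimated correlation), with 0 of 21 called over all genes and 14 lower adjusted over the list alone. Col1a1 stood at 2403 CPM in XEN ESC medium 1, and without that library the list was at adjusted p = 0.107, with a median of -1.86 (quartiles -3.38 to 0.338) against -5.19 (-6.54 to -1.56). Hox genes were lower as a list (12 tested, median -1.14, adjusted p = 0.0111; 0.618 with an estimated correlation), with 1 lower adjusted over the list alone. The list of the NRF2 response to oxidants was lower too (14 tested, median -1.10, adjusted p = 0.0408; 0.688 with an estimated correlation; 4 lower adjusted over the list alone). Imprinted genes (23 tested, median 0.71, adjusted p = 0.0134; 0.648 with an estimated correlation), DNA methylation machinery (8 tested, median 0.76, adjusted p = 0.0352; 0.672) and parietal endoderm (15 tested, median 0.39, adjusted p = 0.0407; 0.797) were higher as lists, with 0 members called over all genes or adjusted over the list alone. Without XEN ESC medium 1, the NRF2 response and DNA methylation machinery lists were at adjusted p = 0.0946 and 0.103. Their medians were then -1.25 (-1.92 to -0.244) and 0.588 (0.332 to 0.729), against -1.10 (-2.04 to -0.190) and 0.760 (0.569 to 0.972), so these losses do not tie the lists to that library. Without XEN ESC medium 7, the parietal endoderm, imprinted, NRF2 response and DNA methylation machinery lists were at adjusted p = 0.973, 0.237, 0.237 and 0.0966. Their medians over the members tested both ways went from 0.393 (-0.191 to 0.788) to 0.0453 (-0.481 to 0.366), from 0.709 (-0.567 to 1.33) to 0.361 (-0.653 to 1.21), from -1.10 (-2.04 to -0.190) to -0.102 (-1.28 to 0.117) and from 0.760 (0.569 to 0.972) to 0.515 (0.418 to 0.678). The epithelial list (median -0.333 to 0.881, adjusted p = 0.000116; 0.653 with an estimated correlation) and the visceral endoderm list (0.727 to 0.553, 0.00152; 0.653) passed upward in that test, and the median of the Hox list went from -1.14 to -0.521 at a kept call.

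edgeR called 0 of 12944 genes in this comparison, with 1770 at an unadjusted p under 0.05 and a lowest adjusted p of 0.0618, while DESeq2 called 530 (74 higher, 456 lower). Groups did not overlap for 9.95% of genes, where chance gives 5.71%. The count was 49 without XEN ESC medium 2, 35 without XEN ESC medium 7 and 5 with no expression filter (Ccnd1, Pkp1, Prkcdbp, S100a4 and Slit3, at -5.34 to -7.82, named after their values were seen).

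The same cell types were also compared in XEN medium. Gata4 was at 559 ± 64.8 CPM in iXEN cells (SD, n = 4) and 797 ± 436 CPM in XEN cells (SD, n = 3), a log2 difference of -0.50 (95% interval -1.39 to 0.39). Sox17 was at 288 ± 97.5 and 308 ± 49.7 CPM (-0.09, -0.89 to 0.72), and Gata6, Sox7 and Dab2 lay at -0.29 (-1.34 to 0.76), 0.10 (-2.63 to 2.83) and -0.21 (-0.90 to 0.48). Cdh1 lay at 3.15 ± 5.14 CPM in iXEN cells and 64.8 ± 86.8 CPM in XEN cells, with 164 CPM in XEN 7 (-4.42, -7.91 to -0.92), and Afp at -3.20 (-5.66 to -0.75), but neither passed the adjustment (adjusted p = 0.985 for both).

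Epithelial genes were lower in iXEN cells as a list (16 tested, median -1.09, adjusted p = 6.26e-05; 0.605 with an estimated correlation), as were endothelial genes (9 tested, median -1.71, adjusted p = 0.000506; 0.607), visceral endoderm genes (14 tested, median -0.60, adjusted p = 0.0101; 0.537), cell cycle genes (24 tested, median -0.22, adjusted p = 0.0141; 0.797) and trophoblast genes (7 tested, median -0.42, adjusted p = 0.0243; 0.605). XEN 7 held 708 CPM of the keratin Krt19 and 649 CPM of Vwf in this medium. Fibroblast genes were higher (18 tested, median 3.45, adjusted p = 0.0101; 0.790 with an estimated correlation), and Col1a1 was at 393 and 391 CPM in iXEN XEN medium 2 and 9. In each of these lists 0 genes were called over all genes and 0 adjusted over the list alone. Without iXEN XEN medium 2 and 9, the fibroblast list turned downward (adjusted p = 0.0373; 0.778 with an estimated correlation), with a median over the 15 members tested both ways of -1.77 (quartiles -2.70 to -0.588) against 2.26 (0.479 to 4.85). The cell cycle call was lost (0.144), its median going from -0.220 (-0.343 to -0.150) to 0.143 (0.0658 to 0.367). The visceral endoderm and trophoblast lists were at adjusted p = 0.261 and 0.0939, with medians of -0.708 (-1.62 to 0.246) and -1.68 (-1.99 to -0.0576) against -0.603 (-1.19 to -0.302) and -0.422 (-2.04 to 0.0403), so these 2 losses do not tie the lists to those libraries. The Hox list passed downward (median 0.565 to -1.17, adjusted p = 0.0168; 0.778 with an estimated correlation), and at kept calls the epithelial median went from -1.09 to -0.506 and the endothelial median from -1.71 to -2.69. Without XEN 7 the endothelial median went from -1.71 to -0.440 (adjusted p = 0.0181; 0.669 with an estimated correlation), the epithelial median from -1.09 to -0.526 and the trophoblast median from -0.422 to -0.858, all at kept calls. The endothelial members without XEN 7 had quartiles of -1.07 to 2.01 and a mean of 0.125, against -4.90 to -0.975 and -2.44 with it. They no longer lay on 1 side. The Hox (median 0.735 to 1.93, adjusted p = 0.0361; 0.710 with an estimated correlation), FGF-ERK response (-0.0664 to 0.780, 0.0361; 0.653), hypoxia and glycolysis (0.348 to 0.383, 0.0295; 0.653) and interferon lists (1.65 to 2.01, 0.00215; 0.653) then passed upward and the XEN core list downward (-0.226 to -0.268, 0.0455; 0.653).

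edgeR called 0 of 13263 genes, with 544 at an unadjusted p under 0.05 and a lowest adjusted p of 0.174, while DESeq2 called 134 (94 higher, 40 lower). Groups did not overlap for 4.55% of genes, below the 5.71% that chance gives.

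The effect of 5 passages in XEN medium was examined in XEN cells. Sox17 was at 308 ± 49.7 CPM in XEN medium and 285 ± 76.3 CPM in ESC medium (SD, n = 3 each), a log2 difference of 0.08 (95% interval -0.70 to 0.85). Gata4 lay at -0.08 (-1.62 to 1.46), Gata6 at 0.54 (-0.71 to 1.79), Dab2 at -0.48 (-1.78 to 0.82), Ttr at -1.10 (-3.08 to 0.88) and Afp at -2.16 (-6.77 to 2.45). Cell cycle genes were higher as a list in XEN medium (24 tested, 22 with a positive difference, median 0.56, adjusted p = 1.24e-05; 0.634 with an estimated correlation). Genes of cholesterol synthesis were also higher (18 tested, median 0.47, adjusted p = 0.00468; 0.605), as were pluripotency genes (11 tested, median 0.52, adjusted p = 0.0399; 0.605), of which 1 was higher adjusted over the list alone.

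Genes of the fibroblast list were lower in XEN medium (19 tested, median -2.95, adjusted p = 3.54e-05; 0.607 with an estimated correlation), with Col1a1 at 2403 CPM in XEN ESC medium 1; without that library the median went from -2.95 to -1.02 and the adjusted p was 0.00711 (0.778 with an estimated correlation). Genes of hypoxia and glycolysis (15 tested, median -0.57, adjusted p = 0.0407; 0.605) and interferon genes (14 tested, median -2.68, adjusted p = 0.0224; 0.797) were lower as lists. Except for the pluripotency gene, 0 members of these lists were called over all genes or adjusted over the list alone. The interferon call was lost without XEN ESC medium 1 (adjusted p = 0.962), where the median went from -2.68 (-3.60 to -1.86) to -0.0626 (quartiles -1.22 to 0.223). Without XEN 7, the interferon and pluripotency lists were at adjusted p = 0.235 and 0.209, with medians over the 9 and 11 members tested both ways of -3.32 (-4.32 to -1.34) and 0.580 (0.120 to 1.51) against -2.44 (-2.85 to -0.814) and 0.516 (0.0541 to 1.31), so these losses do not tie the lists to XEN 7. The epithelial (median -0.0350 to 0.649, adjusted p = 0.00870; 0.653 with an estimated correlation) and trophoblast lists (0.649 to 1.12, 0.00861; 0.653) passed upward in that test. Without XEN ESC medium 1 the medians of the cholesterol synthesis (0.468 to 0.704) and pluripotency lists (0.516 to 0.846) moved at kept calls. With the XEN number as a block, the trophoblast, NRF2 response and DNA methylation machinery lists passed (adjusted p = 0.0300, 0.0148 and 0.0496, against 0.0571, 0.0816 and 0.0924 without it), and with an estimated correlation none of the 3 did (0.798 each).

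edgeR called 0 of 13241 genes, with 746 at an unadjusted p under 0.05 and a lowest adjusted p of 0.800, while DESeq2 called 89 (20 higher, 69 lower). Groups did not overlap for 12.8% of genes, where chance gives 10% if the libraries are not paired, and the blocked fit also called 0 genes.

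In iXEN cells the same change of medium went with lower values of several endoderm genes, none of which passed edgeR's adjustment. Gata4 was at 1071 ± 146 CPM in ESC medium and 559 ± 64.8 CPM in XEN medium (SD, n = 4 each), a log2 difference of -0.92 (95% interval -1.44 to -0.39, adjusted p = 0.0852). Dab2 was at 1028 ± 115 and 404 ± 119 CPM (-1.33, -1.93 to -0.72, adjusted p = 0.0585), and Ttr at 80.6 ± 66.8 and 12.8 ± 9.35 CPM (-2.62, adjusted p = 0.119). Afp lay at -2.92 (-4.85 to -0.99, adjusted p = 0.111), Gata6 at -0.09 (-0.83 to 0.64) and Sox17 at 0.64 (-0.18 to 1.47). Nanog was at 0.469 ± 0.141 and 1.48 ± 0.168 CPM (1.68, adjusted p = 0.0972). DESeq2 called Gata4, Dab2, Afp, Ttr and Nanog (adjusted p = 0.00305, 0.000418, 0.00558, 0.0142 and 0.00637).

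Visceral endoderm genes were lower as a list in XEN medium (16 tested, median -1.61, adjusted p = 0.00352; 0.605 with an estimated correlation), with 9 lower and 2 higher adjusted over the list alone. Parietal endoderm genes (15 tested, 3 lower adjusted over the list alone, median -0.99, adjusted p = 0.00599; 0.605) and imprinted genes (24 tested, 3 lower adjusted over the list alone, median -0.46, adjusted p = 0.00289; 0.605) were lower too. Epithelial genes (16 tested, 2 lower adjusted over the list alone, median -1.27, adjusted p = 0.00630; 0.680) and endothelial genes (6 tested, 1 lower adjusted over the list alone, median -1.42, adjusted p = 0.00951; 0.607) followed. Cholesterol synthesis genes were higher (17 tested, 5 higher adjusted over the list alone, median 0.66, adjusted p = 0.00319; 0.737 with an estimated correlation). None of these members was called by edgeR over all genes. Without iXEN XEN medium 2 and 9, which held 393 and 391 CPM of Col1a1, the visceral endoderm and epithelial lists were at adjusted p = 0.0537 and 0.242. Their medians over the members tested both ways were then -1.98 (-3.12 to 0.519) and -0.716 (-1.20 to 0.250), against -1.61 (-3.01 to -0.0177) and -1.27 (-1.71 to -0.0239), so the first loss does not tie the visceral endoderm list to those libraries. The fibroblast list (median 4.47, adjusted p = 0.223) was then lower (-2.01 (quartiles -5.34 to -0.897), adjusted p = 5.40e-06) and the cell cycle list (median 0.26, adjusted p = 0.142) higher (0.611 (quartiles 0.488 to 0.933), adjusted p = 2.60e-05) in XEN medium, and with an estimated correlation both were at 0.778. The imprinted median went from -0.456 to -1.89 at a kept call.

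edgeR called 0 of 12920 genes, with 3018 at an unadjusted p under 0.05 and a lowest adjusted p of 0.0581, while DESeq2 called 1637 (949 higher, 688 lower). Groups did not overlap for 1553 of these genes, where chance gives 2.86% of genes. The count was 416 without iXEN ESC medium 6, 346 without iXEN XEN medium 2, 330 in a fit over all 17 libraries and 1 without iXEN XEN medium 2 and 9 (Dpcr1, -4.60, named after its value was seen).

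Whether the medium acted differently on iXEN and XEN cells was tested as an interaction over the 14 XEN and iXEN libraries. The log2 difference of the medium changes, iXEN minus XEN, was -0.85 for Gata4 (95% interval -2.20 to 0.50), -0.65 for Gata6 (-1.95 to 0.66), 0.55 for Sox17 (-0.55 to 1.66) and -0.86 for Dab2 (-2.08 to 0.35). Thy1 lay at 17.94 and Sox2 at 15.82 (edgeR adjusted p = 0.221 for both); DESeq2 called Sox2 (0.00158). As given above, 216 CPM of Thy1 in XEN ESC medium 1 and 48.2 CPM of Sox2 in iXEN XEN medium 9 enter these values.

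Fibroblast genes differed as a list (24 tested, 15 higher adjusted over the list alone, median 11.35, adjusted p = 7.18e-05; 0.672 with an estimated correlation), as did Hox genes (22 tested, 9 higher adjusted over the list alone, median 5.16, adjusted p = 0.00173; 0.672) and interferon genes (15 tested, 0 adjusted over the list alone, median 4.26, adjusted p = 0.0399; 0.797). Epithelial genes (17 tested, 1 lower adjusted over the list alone, median -1.62, adjusted p = 0.00172; 0.605), visceral endoderm genes (19 tested, 0 adjusted over the list alone, median -1.49, adjusted p = 0.0182; 0.605) and DNA methylation machinery (8 tested, 1 lower adjusted over the list alone, median -1.28, adjusted p = 0.00977; 0.605) lay on the negative side. Without the numbers of the 3 libraries with fibroblast collagens, the epithelial list kept its call (adjusted p = 2.22e-05; 0.778 with an estimated correlation). The calls of the fibroblast (0.708, downward), Hox (0.602), visceral endoderm (0.343), DNA methylation (0.139) and interferon lists (0.0863, downward) were lost. Over the members tested both ways, their medians went from 9.74 (2.40 to 13.4) to -0.436 (-2.06 to 1.63), from 2.55 (0.242 to 5.50) to 0.0835 (-0.897 to 0.834), from -1.49 (-1.98 to -0.766) to -0.0572 (-1.76 to 1.11), from -1.28 (-1.52 to -0.849) to -0.736 (-1.24 to -0.0902) and from 4.27 (2.43 to 5.17) to -1.31 (-1.78 to -0.515). The imprinted (median -0.447 to -0.697, adjusted p = 4.30e-05; 0.778 with an estimated correlation) and endothelial lists (-1.69 to -2.05, 0.00519; 0.778) passed downward in that test. Without XEN 7 the trophoblast (median -0.684 to -0.876, adjusted p = 0.0416; 0.653 with an estimated correlation), endothelial (-1.69 to -0.418, 0.0350; 0.653) and cell cycle lists (-0.370 to -0.566, 0.0252; 0.710) passed downward, and the DNA methylation median went from -1.28 to -0.824 at a kept call.

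edgeR called 0 of 14357 genes for the interaction, with 2131 at an unadjusted p under 0.05 and a lowest adjusted p of 0.221, while DESeq2 called 498 (438 higher, 60 lower). The medium changes of the 2 cell types, taken per number, did not overlap for 13.6% of genes, where chance gives 5.71%. This share treats libraries of the same number as pairs, which the check of the numbers did not bear out for iXEN cells.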

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

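The tests of the fibroblast transcripts, of the Y-linked counts and of XEN 7 were all chosen after their results were seen, as were the libraries and example genes they concern.

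In groups of 4 libraries, a library was marked when its gap to the nearest other library took up most of the group's range (Dixon's test at 95%), which chance gives in about 1 of 20 groups. Of 129 tests on the named genes, 8 were marked, where 6.45 are expected by chance. In iXEN ESC medium 6, Anxa13 was at 0.0461 CPM against 13.8 to 23.1 CPM in the other libraries (gap over range 0.904), Slc38a5 at 1.29 against 21.1 to 35.7 CPM (0.840) and Lama1 at 16889 against 26153 to 28361 CPM (0.844). In iXEN XEN medium 6, Gata6 was at 551 against 223 to 259 CPM (0.834) and Dab2 at 582 against 329 to 359 CPM (0.847). In iXEN XEN medium 9, Sox17 was at 144 against 318 to 356 CPM (0.874) and Hnf4a at 7.44 against 13.6 to 14.3 CPM (0.916). In iXEN XEN medium 1, Cdh1 was at 10.9 against 0.492 to 0.692 CPM (0.897).

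The medium change differed between iXEN and XEN cells for 6 gene lists in the interaction test, with adjusted p of 0.0182 for visceral endoderm, 7.18e-05 for fibroblast, 0.00172 for epithelial, 0.00173 for Hox, 0.0399 for interferon and 0.00977 for DNA methylation machinery. None of them passed with an estimated correlation. Without the numbers of the libraries with fibroblast collagens, only the epithelial list among them kept its call, as given above.

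In XEN ESC medium 1, iXEN XEN medium 2 and iXEN XEN medium 9, 67 genes that were above 100 CPM in MEF and under 1 CPM in 5 other XEN-medium libraries lay at a median of 6.22%, 4.04% and 1.56% of their MEF level. Fibroblasts like the sequenced MEF, or reads of the MEF libraries, would bring all abundant MEF transcripts; over the 3 libraries together both tests of such mixing were undecided, and only then were the libraries tested separately. In iXEN XEN medium 2 and 9, 3 and 7 of the 107 genes above 1000 CPM in MEF lay under 0.1 of the level needed (Igf2 and H19 in both), the first count exactly at its bound of 3, and the 90th to 10th percentile ratio of the share was 64.7 and 579.5, over its bound of 30 and against 1.80 to 2.86 in MEF libraries, which argues against mixing in these libraries. In XEN ESC medium 1 the count was 2, again Igf2 and H19, at 0.0555% and 0.357% of their MEF level, which goes against mixing, but with the count under 3 and the ratio at 15.6, between its bounds, mixing may explain its transcripts and stays open there. That cells with few endoderm transcripts make up a large part of these cultures also stays open, with medians of the XEN core genes at 0.0442, -0.43 and -0.59 from the rest of the group (log2; median absolute deviations 0.98, 0.82 and 0.59), and no biological explanation from the design was tested.

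Y-linked genes summed to 0.261 CPM in iXEN ESC medium 9 and 61.4 CPM in iXEN XEN medium 9, and to 69.3 CPM in iXEN ESC medium 6 and 0.0301 CPM in iXEN XEN medium 6, while Xist was at 2239, 0.463, 3.37 and 0.812 CPM in these libraries. The ratio for number 9 was 235 (95% counting interval 114 to 568), which argues against 1 unchanged line under that number in both media. An exchange of numbers 6 and 9 in 1 medium would match the Y-linked sums, but Xist was 2756.6 times higher in iXEN ESC medium 9 than in iXEN XEN medium 6 (95% counting interval 1894 to 4183), which argues against an exchange of lines otherwise unchanged. An exchange with a change of Xist in 1 of the lines was to be supported by both crossed correlations of the deviations from the group means above 0.1 and opposed by both below those of the same numbers (0.17 and -0.11); they were 0.24 and -0.00612, which meets neither, so it stays open. A single wrong label and the loss of a Y chromosome in culture were not tested, nor was any biological explanation from the design.

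XEN 7 stood apart in both media, with Sox7 at 0.470 and 0.805 CPM against at least 40.7 CPM in the other 12 XEN and iXEN libraries, with Cdh1 at 214 and 164 CPM, and with Xist at 716 and 1091 CPM where Y-linked genes summed to 0.0261 and 0.0196 CPM. Of 6694 genes with at least 10 CPM in all of those 12 libraries, 43 lay more than 10-fold below the median difference of these genes in both libraries of XEN 7, among them Sox7, Thbd, Cited1 and Pth1r. Cells mixed into a culture otherwise like XEN 1 and 2 could not lower so many genes this far without replacing most of it, and the bound was 10 genes, which argues against such mixing as the whole cause. Female sex may play a part and stays open: the deviations of XEN ESC medium 7 and iXEN ESC medium 9, the other library with high Xist, correlated at -0.196 across genes, which are not independent replicates, between the bounds of -0.3 and 0.3. A different origin of this line was not tested, and no biological explanation from the design was tested.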

How the results depend on the processing

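Tests without the libraries that held fibroblast collagens, without XEN 7 or without both, and list tests with RLE size factors or a block, were chosen after the results were seen; where a value below changed, the cause was not tested. Without both, XEN 2 was the lone XEN library in ESC medium (for the interaction, in each medium) and was assumed to vary like the other groups, so these values show that library only. Against MEF the spread then came from MEF alone, whose libraries varied less than those of XEN cells.

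edgeR called 6704 genes for iXEN against MEF, 4476 to 7849 under the other settings and 5064 to 8081 when single libraries were left out. DESeq2 shared 6654 of these calls, and the XEN-medium libraries shared 3314, 3310 of them with the same sign. For XEN against MEF the count was 3507, with 5850 by DESeq2, 6830 with the XEN-medium libraries, 7911 without XEN ESC medium 1 and 7 (XEN ESC medium 2 alone), and 372 to 6056 when single libraries were left out. All 372 genes called without MEF 1 and 3353 of the 7911 were among the 3507. The other 5 comparisons had 0 calls. DESeq2 called 530 and 134 genes for iXEN against XEN in ESC and XEN medium, 89 and 1637 for the medium in XEN and iXEN cells, and 498 for the interaction. For iXEN against XEN in ESC medium, no filter gave 5, leaving out XEN 7 gave 35, leaving out XEN ESC medium 1 and 7 gave 12 (XEN ESC medium 2 alone), and leaving out single libraries 0 to 49. For the medium in iXEN cells, 1 fit over all 17 libraries gave 330, leaving out iXEN XEN medium 2 and 9 gave 1, and leaving out single libraries 0 to 416. Leaving out single libraries gave 0 to 0 for iXEN against XEN in XEN medium, for the medium in XEN cells and for the interaction (a number at a time in both media). The overlap of iXEN vs MEF and XEN vs MEF held 2974 genes called in the same direction, 2640 with a log2 fold change of at least 1, and 5646 without XEN ESC medium 1 and 7, where 14 went opposite ways and XEN ESC medium 2 alone stood for XEN cells.

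With the replicate block, XEN against MEF had 1303 calls, iXEN against XEN in ESC medium 9, and the interaction 1 (Zfp575, 10.18, adjusted p = 0.0466, named after its value was seen). MEF and the other cells share only numbers, as do XEN and iXEN cells. The same numbers of iXEN libraries correlated at 0.25, 0.23, 0.17 and -0.11 across media for 1, 2, 6 and 9, so they do not pair these libraries. Not every one correlated best with its own number, which also held for XEN ESC medium 2. For the medium in XEN cells, where the numbers passed the threshold of 0.1, the block passed the 3 lists given with that comparison and changed no other call. The interferon median went from -2.68 to -1.76 at its kept call. List tests passed in 54 cases, in 58 with RLE size factors, in 61 with the block (48 shared), and in 0 with an estimated correlation, with or without the block and in each test below. Without the libraries with fibroblast collagens 32 passed against 42 in the same comparisons (27 shared, 26 in the same direction), without XEN 7 43 against 36 (30 shared), and without both 43 against 36 (25 shared, 22 in the same direction), where 4 of the 5 comparisons had XEN 2 as a lone library.

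Sox2 changed sign for iXEN against MEF with the XEN-medium libraries (2.45, adjusted p = 0.459) and for XEN against MEF with the XEN-medium libraries (-6.95, adjusted p = 0.00355). Cdh1 (-3.91, adjusted p = 0.0323) and Nanog (-2.09, adjusted p = 0.0316) did so for XEN against MEF without XEN ESC medium 1 and 7, where they are values of XEN ESC medium 2 alone. Of 772 values of 60 named genes called for iXEN against MEF, 746 kept direction and call, as did 643 of 742 values of 50 genes for XEN against MEF. Under every setting that tested them, 41 of the 60 and 22 of the 50 genes kept both. Most of these genes were picked from the same fits for large changes, so the shares do not stand for all called genes. Over genes with an average logCPM of at least 3, the biological coefficient of variation was 0.149 in MEF, 0.537 in XEN and 0.368 in iXEN cells in ESC medium, and 0.438 and 0.490 in XEN medium. Depth limits genes with 0 to 3 counts in a group, whose folds are given as bounds or with counting intervals.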

Other observations

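The tests of opposite signs and of other splits were set before their results were seen; the other splits and other sets of libraries used for the opposite signs and the test of the neighbours of Col4a1 and Col4a2 were chosen after, as were the example genes.

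Against MEF, pluripotency genes went both ways, with 7 of 12 higher and 2 lower in iXEN cells (8 and 3 adjusted over the list alone; median 1.94, adjusted p = 0.0571) and 3 of 10 higher and 1 lower in XEN cells (4 and 1; 0.97, 0.113). The RNA-binding protein gene Lin28a rose by 10.15 (SE 0.52) and 9.14 (SE 0.38) and Tfcp2l1 by 5.03 and 4.68, while Klf2 fell (-2.60 and -3.40). Of 17 STAT3 response genes, 5 rose and 8 fell in iXEN cells (the same counts adjusted over the list alone; median -1.58, adjusted p = 0.602) and 3 rose and 5 fell in XEN cells (4 and 7; -0.85, 0.577). The receptor subunit Il6st fell (-3.27 and -3.97), and Lifr rose by 3.02 in iXEN cells. Of 15 FGF-ERK response genes, 2 rose and 7 fell in iXEN cells (2 and 8; median -1.76, adjusted p = 0.154) and 1 rose and 4 fell in XEN cells (1 and 4; -0.80, 0.151), and Spry1 fell in iXEN cells (-7.44). Of 12 BMP and Nodal genes, 3 rose and 5 fell in iXEN cells (median -0.43, adjusted p = 0.714), and 2 rose and 2 fell in XEN cells (-0.48, 0.680), with the same counts adjusted over the list alone. The ligand gene Bmp4 fell (-7.69 and -3.75) and Bmp2 rose by 4.55 and 4.42. Of the WNT response genes, 2 of 10 rose and 4 fell in iXEN cells (3 and 4; median -0.41, adjusted p = 0.819), and 1 of 11 fell in XEN cells (0; -0.64, 0.777), with Lgr5 at -8.02 in iXEN cells and -5.81 in XEN cells. In the hypoxia and glycolysis list, 5 of 16 rose and 5 fell in iXEN cells (6 and 5; median 0.25, mean -0.13, test upward, adjusted p = 0.652), and 4 rose and 2 fell in XEN cells (4 and 2; median 0.17, adjusted p = 0.602), with the hexokinase Hk2 at 2.30 and 1.95.

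Of 17 p53 and CDK inhibitors, 7 fell and 0 rose in iXEN cells (6 adjusted over the list alone; median -0.63, adjusted p = 0.151), and 3 fell in XEN cells (3; -0.36, 0.583); Cdkn1c (-6.47) and Cdkn2b (-2.68) were among the falls in iXEN cells. Of 14 NRF2 response genes, 3 rose and 5 fell in iXEN cells (3 and 7; median -0.53, adjusted p = 0.602), and 2 rose and 1 fell in XEN cells (2 and 1; 0.27, 0.677), with the quinone reductase Nqo1 at -4.44 in iXEN cells. Of 16 genes of the integrated stress response, 1 rose and 1 fell in iXEN cells (0 and 1; median 0.36, mean 0.11, test downward, adjusted p = 0.863) and 1 rose in XEN cells (0; -0.12, 0.652), Psph rising by 2.04 and 1.89. In the DNA methylation machinery list, 3 of 8 rose and 1 fell in iXEN cells (median 0.78, adjusted p = 0.299) and 1 of 7 rose and 1 fell in XEN cells (0.05, 0.889), with the same counts adjusted over the list alone; the methyltransferase Dnmt3b rose by 3.67 and 3.12 and Dnmt3a fell (-0.70 and -1.27). Of 9 germline genes, 4 rose and 1 fell in iXEN cells (the same adjusted over the list alone; median 0.08, adjusted p = 0.539), and of 4 in XEN cells 1 rose and 1 fell; Tex19.1 had 1 count in MEF and ratios of 1940.1 (348 to 76657) and 1789 (321 to 70688). Neural genes had 3 of 6 lower in iXEN cells (3; median -2.19, adjusted p = 0.0583), Map2 at -9.33 among them, and 0 of 6 in XEN cells (0; -1.21, 0.299). Of 5 trophoblast genes, 1 rose and 1 fell in iXEN cells (1 and 1; median 0.74, adjusted p = 0.798), and of 4 in XEN cells 0 changed. Of 4 primitive streak genes, Foxf1 fell in iXEN cells (-2.71) and 0 changed in XEN cells. Of 5 sex-linked genes, Xist rose in iXEN cells (10.30, SE 3.21; 0 genes adjusted over the list alone), with 2239 CPM in iXEN ESC medium 9 and 1.93 to 9.53 CPM in the other 3 libraries, and 0 changed in XEN cells. Of the reprogramming factors, 2 of 4 rose and 1 fell in iXEN cells, and 0 of 3 changed in XEN cells, also adjusted over the list alone. None of these set tests passed with an estimated correlation.

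The log2 differences of iXEN from XEN cells in ESC medium and in XEN medium had a Pearson correlation of -0.249 across 12660 genes, which are not independent replicates, and the medium changes of XEN and of iXEN cells one of -0.240 across 12665 genes. A hypothesis was that the libraries with fibroblast collagens, which lie on opposite sides of these differences, may bring the negative sign. Without those 3 libraries the correlations were 0.245 and 0.122 (Spearman's rho from -0.315 to -0.00398 and from -0.113 to 0.137), where a value of 0 or above was set as the mark of this cause and one below -0.2 as evidence against it. For the differences from XEN cells that mark cannot decide. Without these libraries all 34 other splits of the 7 numbers also lay above 0, at 0.220 to 0.593 with a median of 0.443. With all libraries the other splits lay at -0.297 to 0.549 with a median of 0.289, and 28 of the 34 were at 0 or above. The real split lay near the lowest of them both ways (-0.249 and 0.245), so this cause stays open. The medium changes of XEN and iXEN cells share no library, and leaving out 4 of 18 sets of 1 XEN ESC-medium and 2 iXEN XEN-medium libraries brought their correlation above 0, among them all 3 sets with iXEN XEN medium 2 and 9 (0.122, 0.140 and 0.179), whichever XEN library was left out.

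Other splits of the same libraries were tested for each comparison. For iXEN against MEF, 1 of 35 splits, the real one, called as many as 6704 genes, a share under 0.05. The highest other, MEF with iXEN ESC medium 6, called 2323. This argues against chance but does not exclude it, since 35 splits allow no smaller share and the comparisons were not adjusted together. For XEN against MEF the 10 splits are too few for a share under 0.05, with 3507 calls for the real split and 0 for the highest other. At an unadjusted p under 0.05, iXEN against XEN in ESC medium gave 1770 genes, and 3 of 35 splits gave as many, so chance cannot be excluded. The highest, 4636 genes with 1543 called, set XEN ESC medium 2 and iXEN ESC medium 1, 2 and 9 against XEN 1 and 7 and iXEN 6, which points to a structure of the samples other than cell type. In XEN medium 22 of 35 splits gave as many as the real 544 genes, and the highest other, XEN with iXEN 1, gave 1836 with 0 called, so chance cannot be excluded. The split of XEN 1 and 2 and iXEN 1 and 6 against the other 3 libraries gave 1545 with 104 called, which again points to a structure of the samples. For the medium in XEN cells the 10 splits are too few for a share under 0.05: the real split gave 746 genes and the highest other 2410, and 4 splits gave as many as the real one. Of the 4 splits that part all pairs of numbers, the real one was highest and the next gave 422, while the highest other kept both libraries of XEN 7 together. For the medium in iXEN cells 2 of 35 splits gave as many as the real 3018 genes, the highest other gave 3661 with 436 called against 0, which points to a structure of the samples, and chance cannot be excluded. For the interaction 2 of 35 splits gave as many as the real 2131 genes, the highest other gave 2264, and chance cannot be excluded.

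XEN XEN medium 1 held 6.10 CPM of Col4a1 and 3.13 CPM of Col4a2, neighbouring genes of basement membrane collagen, at -9.88 and -10.17 on the log2 scale from the mean of XEN XEN medium 2 and 7; the other 13 XEN and iXEN libraries held at least 2019 and 1194 CPM. The 10 expressed genes nearest to them in the reference annotation (GRCm38.p6) lay at a median of 0.32 (-1.46 to 0.97). The same library had 16.3 CPM of Y-linked genes in sum, with Ddx3y at 0.0245 CPM. XEN ESC medium 1, which carries the same number, had 123 CPM of Y-linked genes in sum and 39.2 CPM of Ddx3y. It held 13141 CPM of Col4a1. Whether number 1 names 1 unchanged line in both media was not tested. Cdkn2a was at 271, 258 and 213 CPM in XEN ESC medium 1, iXEN XEN medium 2 and iXEN XEN medium 9, against 31.3 CPM in MEF and at most 94.7 CPM in the other 11.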
